A study of Mus musculus with 3 samples.

How the data were processed

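Cardiomyocyte nuclei were isolated from mouse ventricles, and total RNA libraries were made with a stranded low-input kit and sequenced on an Illumina NextSeq as single-end 75 bp reads, per the labels' protocols. Newborn mice received saline or the vectors in 40 µL, per the labels' protocols. The submitters' processing notes list FastQC 0.11.8, Trimmomatic 0.39, HISAT2 2.1.0, featureCounts 1.6.2, DESeq 1.38.0 and the mm10 build, with no role or order. The authors deposited a table of TPM, a read share scaled by gene length and library total, with 53278 symbols and 9 libraries. The annotation and gene lengths behind it are not given in the sources used here.

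TPM sums lay between 994889 and 999337, and 25183 to 32194 genes were above 0 per library. Symbols were matched to GENCODE M21 (GRCm38), where 49587 (93.1%) had 1 gene. TPM times exon length fell on steps within a library. Taking the most common step as a read of 60 bases, 54% to 63% of the low values checked were whole numbers of bases within 0.02 base, where 4% is expected by chance. Depth in read equivalents was estimated from this step. Whole reads were not recovered, so no count model was fitted, and depths and read equivalents are estimates. The interval for the Snord14e ratio alone treats rounded read equivalents as counts. Symbols found more than once (4 entries) were left out, and 26 symbols had the form of a date, as spreadsheets make them.

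Libraries were grouped by column name: names in WT and Het match the titles of the saline samples, and names in Het_AAV were given to the only sample treated with AAV. Values were analysed as log2(TPM + 1), which understates fold changes of low genes. Genes with a mean of at least 5 TPM over all libraries were kept (11849 genes). All 3 groups entered 1 limma fit (limma 3.58.1 in R 4.3.3, eBayes with trend), with a Benjamini-Hochberg adjusted p below 0.05 as the threshold. Of 32 gene lists, 24 with at least 5 measured members were tested with camera at a correlation of 0.01, with an estimated correlation, and with fry, adjusted over lists, and 8 had fewer members. A list score per library was the median of the members after subtracting the library's all-gene median and each gene's WT mean. Groups, tests, lists and the rule for named genes were fixed before the data were examined.

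The rule named 12 genes always; per comparison, up to 10 genes with the largest rise and 10 with the largest fall past the threshold, leaving out predicted genes, clones and pseudogenes; and up to 4 members with the largest difference per described list. Chosen after their values were seen were Snord14a, Snord14c, Snord14d and Hspa8. In the closing section they were Snord15a, Snord17, Stk16, CT010467.1, Gm26917, Snora73b, Gm45841, Gm24029, Chchd10 and Gm23212. So were the mural markers Pdgfrb, Notch3, Cspg4, Des and Abcc9.

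The limma and camera steps were tested on simulated data with the real means and spreads and 200 changed genes among 11849. In HET saline against WT saline, 0.6% of 2-fold, 72% of 4-fold and 92.8% of 8-fold changes passed, with 0.2, 9.2 and 10.4 false calls on average. A shifted list of 42 genes was called in 20 of 20 draws, and 0 of 460 other lists were. Genes were drawn independently, so these draws do not show how often camera calls lists whose members move together. In the real data the estimated correlation ran from -0.093 (mural) to 0.895 (mitochondrially encoded) over the tested lists. Alternatives were pseudocounts of 0.1 and 5, filters of 1 and 20 TPM and none, median-of-ratios and upper quartile rescaling, renormalization without structural RNA or to protein-coding genes, predicted genes left out, limma without the trend, with only the compared groups or with sample weights, size rules of 1.5-fold and 4-fold, and leaving out each library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.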

Results

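RNA from isolated cardiomyocyte nuclei of mouse ventricles was profiled in 3 groups of animals aged 18 weeks. Wild-type mice received saline (WT saline), mice heterozygous for a humanized missense mutation in Myh6 received saline (HET saline), and heterozygous mice received an adenine base editor split over a pair of AAV9 vectors (HET ABE). Myh6 encodes the alpha myosin heavy chain, the main motor protein of the adult mouse ventricle, and an adenine base editor changes A to G without cutting both DNA strands. Chow with cyclosporine A at 1 g/kg was given to hasten hypertrophic cardiomyopathy, in all 3 groups per the labels. The labels give a correction efficiency of about 35% for the edited sample. The deposited table holds 9 libraries: 1, 2 and 3 for WT saline, 6, 7 and 8 for HET saline, and 9, 10 and 11 for HET ABE. The labels give 1 sample per group, so the p-values measure only the spread between the libraries of that sample, which may be technical.

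The table gives TPM and no counts. The steps between low values put the depth at about 30.0, 40.8 and 42.4 M read equivalents in the WT saline libraries, 41.6, 30.7 and 26.9 M in HET saline, and 20.4, 30.8 and 26.4 M in HET ABE. Protein-coding genes took 48.7% ± 1.7 of TPM in WT saline, 39.7% ± 1.52 in HET saline and 42.3% ± 6.77 in HET ABE (SD, n = 3). Small nucleolar RNA took 7.31% ± 1.13, 11.1% ± 1.6 and 11% ± 2.81. In read equivalents, protein-coding genes took 85.5% to 89.3% in WT saline, 83.0% to 83.4% in HET saline and 76.6% to 85.5% in HET ABE. Small nucleolar RNA took 0.117% to 0.155%, 0.18% to 0.232% and 0.155% to 0.326% of read equivalents. TPM is a share of the library, and the median gene lay at a log2 difference of -0.25 in HET saline against WT saline, so list medians are also given relative to all genes.

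The first comparison asked how mutant cardiomyocyte nuclei differed from wild type. A single gene passed the threshold: Snord14e, a C/D box small nucleolar RNA, rose from 1.84 ± 0.322 TPM in WT saline to 99 ± 37.6 TPM in HET saline (SD, n = 3; log2 difference 5.08 ± 0.29, SE; limma adjusted p = 3.78e-05; higher in 3 of 3 libraries). The HET saline libraries were at 140.8, 88.4 and 67.9 TPM, and the WT saline libraries between 1.6 and 2.21 TPM. In read equivalents this was 171 against 3, or after scaling to depth a ratio of 64 with an exact interval of 21.5 to 313 that covers counting error only and rests on estimates rounded to whole reads. Snord14e (ENSMUSG00000064791.1) lies on chromosome 9 at 40804748 to 40804837 of GRCm38, on the plus strand, within Hspa8, a constitutive heat shock protein gene. Of the 10 annotated Hspa8 transcripts, 4 span it, 3 of them as an intron and 1 with an exon over it. Its annotated sequence is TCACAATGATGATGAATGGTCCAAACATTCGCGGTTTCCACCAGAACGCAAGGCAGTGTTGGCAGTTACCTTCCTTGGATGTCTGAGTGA. The nearest of the copies compared, Snord14a at 16 edits, was at 4.33 ± 1.66 and 5.84 ± 2.69 TPM (limma adjusted p = 0.718). The more abundant Snord14c and Snord14d, each 19 edits from it, did not pass (log2 differences 0.46 ± 0.31 and 0.53 ± 0.32, limma adjusted p = 0.513 and 0.466). Hspa8 itself was at 112 ± 16.4 and 89.8 ± 64 TPM (limma adjusted p = 0.566).

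**Figure D1:**
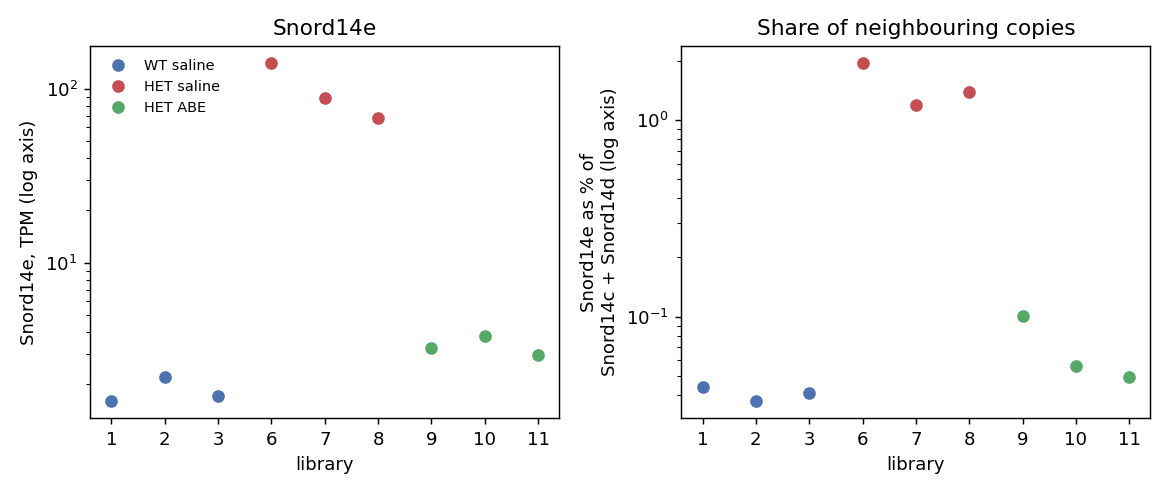
Snord14e in each of the 9 libraries, as TPM in one panel and as a percent of Snord14c plus Snord14d in the other, both on log axes; points are libraries, coloured by group. The HET saline libraries lie between 67.9 and 140.8 TPM and the other libraries between 1.6 and 3.82 TPM.

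The genes of the sarcomere and of cardiac stress did not pass the threshold. Myh6 (chromosome 14, 54941921 to 54966927, minus strand) was at 42500 ± 3223 TPM in WT saline and 31480 ± 3392 TPM in HET saline (log2 difference -0.43 ± 0.19, limma adjusted p = 0.35), and with upper quartile rescaling the difference was 0.005. Gene-level TPM does not separate the mutant from the normal allele. Myh7, the beta myosin heavy chain, was at 5034 ± 1434 and 4151 ± 487 TPM. The natriuretic peptide gene Nppa was listed at 9.23, 8.09 and 7.9 TPM in WT saline and at 33.1, 11.6 and 0 TPM in HET saline, and Nppb was at 44.5 ± 32.9 and 49.8 ± 48 TPM. The skeletal actin gene Acta1 was at 22 ± 33 and 21.7 ± 22.2 TPM, Ankrd1, a stretch-responsive protein, at 285 ± 164 and 304 ± 212 TPM, and Xirp2, an actin-binding protein, at 87.2 ± 28.4 and 131 ± 9.49 TPM. Atp2a2 and Pln, which encode the SERCA2 calcium pump and its inhibitor, were at 1975 ± 429 and 1888 ± 473 TPM and at 466 ± 188 and 262 ± 21 TPM. Rcan1, a target of calcineurin, was at 9.55 ± 1.75 and 8.45 ± 6.23 TPM, and the collagen gene Col1a1 at 10.5 ± 5.48 and 8.27 ± 6.82 TPM. Postn, a marker of activated fibroblasts, stayed below the filter with a mean of 2.57 TPM.

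**Figure D2:**
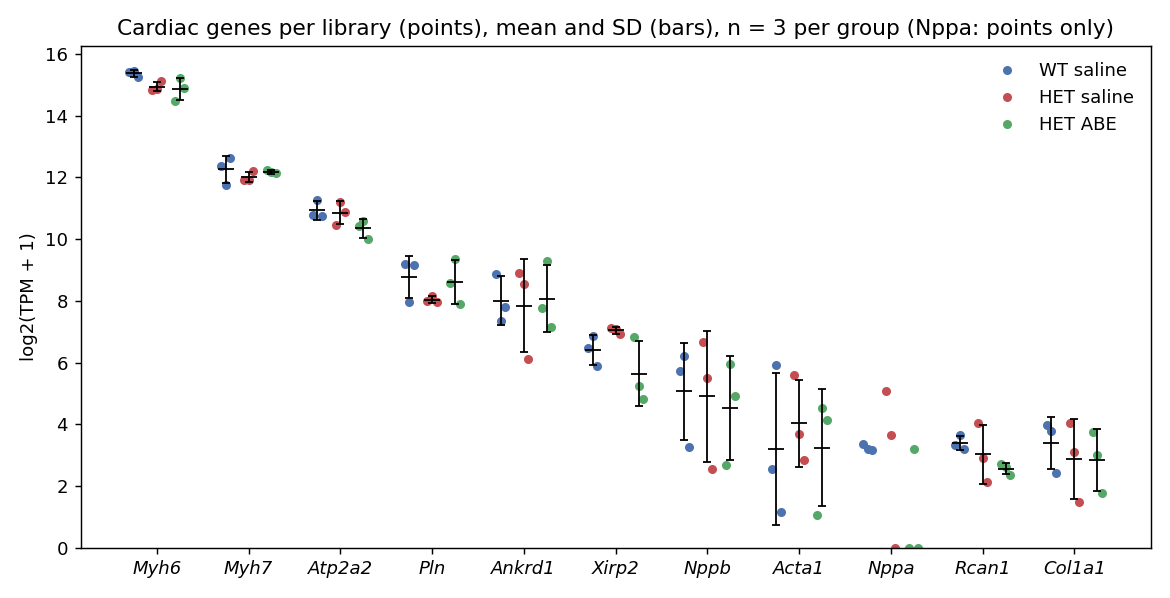
Values of 11 cardiac genes as log2(TPM + 1), with 1 point per library and bars for the mean and SD of each group (n = 3); Nppa is shown as points only because it is listed at 0 in some libraries. None of these genes passed the threshold in any of the 3 comparisons.

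Of the 27 measured sarcomere genes, 20 were lower and 7 higher in HET saline and none passed, with a median log2 difference of -0.25 (camera adjusted p = 0.906). Relative to all genes the median was 0.003, with 12 members below the all-gene median and 15 above it. The cardiac troponin T gene Tnnt2 was at 33580 ± 5120 TPM in WT saline and 20580 ± 2014 TPM in HET saline (limma adjusted p = 0.295). Mybpc3, cardiac myosin-binding protein C, was at 2163 ± 313 and 1387 ± 332 TPM (limma adjusted p = 0.313). Lists of hypertrophic cardiomyopathy genes (camera adjusted p = 0.701), calcium handling (0.814), calcineurin and MEF2 signalling (0.581) and the fetal and stress programme (0.576) were not called either. All groups had cyclosporine chow, so these lists do not describe the mutation without that drug. Without library 8 the fetal and stress list was called higher (0.0429, relative median 0.34 against 0.07).

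Endothelial and fibroblast markers, interferon genes and matrix genes were lower in HET saline as lists. All 11 measured endothelial markers were lower, by a median log2 difference of -1.24 (-0.99 relative to all genes; camera adjusted p = 5.74e-06 and adjusted p = 0.756 with an estimated correlation); 0 passed over all genes and 9 when adjusted over the list alone. Cdh5, the vascular cadherin, was at 15.3 ± 2.83 TPM in WT saline and 3.66 ± 1.55 TPM in HET saline, the water channel gene Aqp1 at 11.2 ± 3.12 and 3.73 ± 2.06 TPM, and Vwf, von Willebrand factor, at 12.1 ± 0.16 and 4.13 ± 2.06 TPM. All 14 fibroblast markers were lower (median -0.86, -0.60 relative; camera adjusted p = 0.00163 and adjusted p = 0.756 with an estimated correlation), with 0 passing over all genes and 2 when adjusted over the list alone. Abca8a was at 88.6 ± 47.2 and 24.1 ± 15.5 TPM, and the intermediate filament gene Vim at 67.7 ± 27.5 and 28.8 ± 22.5 TPM. Of 18 interferon and innate immune genes, 17 were lower (median -0.95, -0.70 relative; camera adjusted p = 0.00198 and adjusted p = 0.756 with an estimated correlation), with Stat2 at 41.6 ± 3.9 and 15.7 ± 11.9 TPM and Irf7 at 9.85 ± 0.848 and 3.84 ± 1.21 TPM. Of 21 extracellular matrix genes, 18 were lower (median -0.83, -0.58 relative; camera adjusted p = 0.0332 and adjusted p = 0.89 with an estimated correlation), with Dcn, which encodes decorin, at 29.8 ± 2.89 and 13.9 ± 5.78 TPM. In these last lists 0 genes passed, over all genes or adjusted over the list alone. All 7 macrophage markers were lower (median -0.71, -0.46 relative) and missed the call (camera adjusted p = 0.0705), which they passed with median-of-ratios (0.0266) and upper quartile rescaling (0.0464), without structural RNA (0.0471), with protein-coding genes alone (0.00166), with the 1 TPM filter (0.00027), with no filter (5.11e-07) and without library 11 (0.0447). Of 5 erythroid markers, 4 were lower (median -1.38, -1.13 relative) and 3 passed when adjusted over the list alone; the list was not called (0.168) except with upper quartile rescaling (0.0171) or no filter (0.0302). The 5 mural markers lay at 0 relative to all genes (0.97) and were called lower with no filter alone (0.035). The lists did not lie alike in each library. Relative to all genes and the WT mean, the fibroblast score was -0.07, -0.87 and -0.97 in libraries 6, 7 and 8. In the same order, the interferon score was -0.03, -0.88 and -1.06, and the matrix score 0.149, -0.726 and -0.788. The endothelial score was -0.44, -1.60 and -0.96, and the erythroid score -0.16, -1.70 and -1.82. For fibroblast (-0.115 to 0.193) and interferon genes (-0.183 to 0.146), library 6 lay within the WT saline range. For matrix genes library 6 was not lower than WT saline (-0.164 to 0.119). The matrix call was lost without library 1 (camera adjusted p = 0.152), 2 (0.137), 7 (0.214) or 8 (0.199, relative median -0.35) and with predicted genes left out (0.158), and the interferon call without library 8 (0.0935, relative median -0.46). With the 20 TPM filter the fibroblast (0.102), interferon (0.179) and matrix (0.463) calls were lost. The endothelial list kept fewer than 5 members with that filter and was not tested in any comparison.

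**Figure D3:**
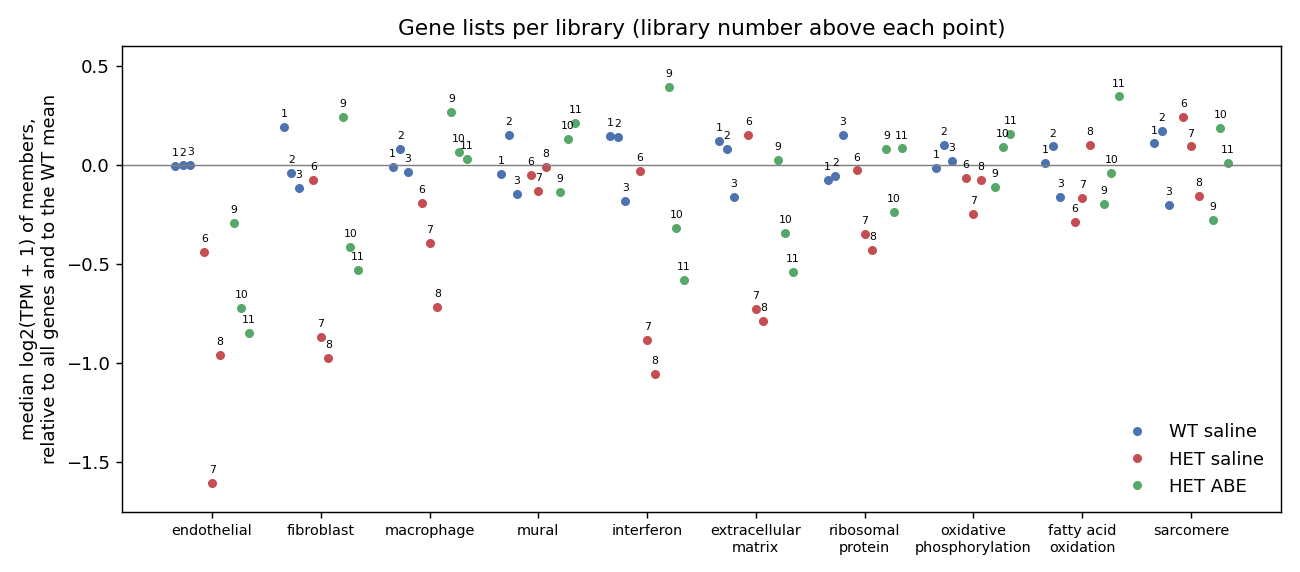
Scores of 10 gene lists in each library, as the median log2(TPM + 1) of the members after subtracting the library's all-gene median and each gene's WT mean; points are libraries, coloured by group. Endothelial scores lie below 0 in all 6 HET saline and HET ABE libraries, from -1.60 to -0.29.

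Of 42 nuclear genes of oxidative phosphorylation, 34 lay below the all-gene median and 41 were lower, by a median of -0.36 (-0.11 relative; camera adjusted p = 0.00163 and adjusted p = 0.756 with an estimated correlation), with 0 passing over all genes and 2 when adjusted over the list alone. The cytochrome c oxidase subunit genes Cox7b and Cox6a2 were at 164 ± 34 and 82.8 ± 10.3 TPM and at 64.5 ± 7.59 and 31.3 ± 6.23 TPM. Of 40 ribosomal protein genes, 31 lay below the all-gene median and 38 were lower (median -0.58, -0.33 relative; camera adjusted p = 0.00184 and adjusted p = 0.756 with an estimated correlation), with Rplp0 at 16.3 ± 0.769 and 5.82 ± 3.95 TPM and Rpl23 at 26.4 ± 7.12 and 12.6 ± 4.17 TPM. Of 31 fatty acid oxidation genes, 24 lay below the all-gene median and 27 were lower (median -0.45, -0.20 relative; camera adjusted p = 0.0489 and adjusted p = 0.756 with an estimated correlation), with the acyl-CoA dehydrogenase genes Acads at 36.5 ± 13 and 14.9 ± 6.79 TPM and Acadvl at 305 ± 50.5 and 165 ± 46.9 TPM. In the ribosomal and fatty acid lists 0 genes passed, over all genes or adjusted over the list alone. Upper quartile rescaling moved the oxidative phosphorylation median to 0.05 along with the all-gene median and ended the call (camera adjusted p = 0.0728), while the relative median stayed at -0.11; rescaling to protein-coding genes ended it too (0.25, relative median -0.02). That relative median was -0.16 without library 1 and -0.19 without library 6, and -0.03 with predicted genes left out, and the ribosomal one was -0.20 without library 7. The fatty acid call was lost with both rescalings (0.0765 and 0.545), with median-of-ratios rescaling (0.118), a pseudocount of 5 (0.0555) or predicted genes left out (0.263), and without library 1 (0.105), 2 (0.215), 6 (0.249), 7 (0.0974) or 9 (0.101). Its relative median was -0.04 without library 6 and -0.29 without library 8. With the 20 TPM filter the ribosomal (0.405) and fatty acid (0.179) calls were lost. Relative to all genes and the WT mean, the ribosomal score was -0.03, -0.35 and -0.43 in libraries 6, 7 and 8. The fatty acid score was -0.29, -0.17 and 0.10, and the oxidative phosphorylation score -0.07, -0.25 and -0.08. Library 6 lay within the WT saline range for ribosomal genes (-0.08 to 0.15). For fatty acid genes, library 8 (0.1) was about level with the top of the WT saline range (-0.161 to 0.093).

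Over the 11849 genes tested with limma on log2(TPM + 1), 172 were higher and 1437 lower at an unadjusted p under 0.05. With no differences, a share of about 0.05 of the genes tested would be expected under this p in each comparison. The counts depended on the scaling, with 557 higher and 523 lower after median-of-ratios rescaling and 1013 higher and 131 lower after upper quartile rescaling. They depended on single libraries too, with 114 higher and 749 lower without library 7, 190 and 812 without library 3, and 135 and 938 without library 1. On simulated data with the real means and spreads, 0.6% of 2-fold, 72% of 4-fold and 92.8% of 8-fold changes were recovered in this comparison.

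The second comparison asked whether base editing moved the mutant profile. No group received vectors without the editor, so editing cannot be told apart from receiving the AAV vectors. Snord14e was again the single gene past the threshold: it fell from 99 ± 37.6 TPM in HET saline to 3.34 ± 0.436 TPM in HET ABE (log2 difference -4.46 ± 0.29, SE; limma adjusted p = 0.000144; lower in 3 of 3 libraries). Myh6 was at 31480 ± 3392 TPM in HET saline and 30460 ± 7368 TPM in HET ABE. Xirp2 was at 131 ± 9.49 and 58.8 ± 46.6 TPM (log2 difference -1.41 ± 0.45, limma adjusted p = 0.592), Atp2a2 at 1888 ± 473 and 1315 ± 259 TPM, and Pln at 262 ± 21 and 423 ± 208 TPM. Nppa was listed at 0, 8.13 and 0 TPM in libraries 9, 10 and 11. In HET ABE, Myh7 was at 4645 ± 197 TPM, Nppb at 32 ± 28.1 TPM, Acta1 at 13.2 ± 10.9 TPM, Ankrd1 at 326 ± 258 TPM, Rcan1 at 4.94 ± 0.743 TPM and Col1a1 at 7.25 ± 5.0 TPM, and none of these genes passed. At an unadjusted p under 0.05, 560 genes were higher and 371 lower, against 454 and 654 after median-of-ratios and 161 and 876 after upper quartile rescaling. They were 284 and 628 without library 9, 813 and 261 without library 11, and 341 and 279 without library 7.

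Of the 7 lists called lower in HET saline, 3 were called higher in HET ABE than in HET saline. Of 40 ribosomal protein genes, 35 were higher (median 0.39, 0.33 relative; camera adjusted p = 0.00748 and adjusted p = 0.919 with an estimated correlation), with Rps15 at 5.93 ± 2.94 TPM in HET saline and 16.1 ± 12.4 TPM in HET ABE and Rpl7 at 8.51 ± 5.64 and 17.1 ± 11.4 TPM. Rplp2 went the other way, at 33.9 ± 6.39 and 13.2 ± 2.67 TPM, and was the 1 member to pass when adjusted over the list alone, with 0 over all genes. Of 42 oxidative phosphorylation genes, 32 were higher (median 0.16, 0.10 relative; camera adjusted p = 0.00748 and adjusted p = 0.919 with an estimated correlation), with Cox7b at 82.8 ± 10.3 and 157 ± 5.32 TPM; with upper quartile rescaling the median was -0.04 and the list stayed higher relative to other genes (camera adjusted p = 0.0239). Of 14 fibroblast markers, 11 were higher (median 0.51, 0.45 relative; camera adjusted p = 0.027 and adjusted p = 0.919 with an estimated correlation), with Gsn, which encodes gelsolin, at 58.4 ± 4.33 and 139.6 ± 110.1 TPM. In the last pair of lists 0 genes passed, over all genes or adjusted over the list alone. All 3 calls were lost without library 7 (camera adjusted p = 0.0688), the fibroblast call also without library 8 (0.17) or 9 (0.31), the oxidative phosphorylation call without library 10 (0.0611) or 11 (0.0555), and the ribosomal call without library 11 (0.0507). The fibroblast call was also lost with predicted genes left out (0.0515) or the 20 TPM filter (0.0917), and the ribosomal call with that filter (0.37). The relative fibroblast median was 0.74 without library 6 and 0.23 without library 9, and that of oxidative phosphorylation 0.18 without library 6, 0.06 without 7, 0.25 without 9 and 0.16 without 10. Endothelial markers (10 of 11 higher, median 0.47), macrophage markers (7 of 7, 0.48), interferon genes (15 of 18, 0.45) and fatty acid oxidation genes (21 of 31, 0.36) were not called (camera adjusted p = 0.0557 for each), nor were matrix genes (13 of 21, 0.19; 0.673). Calls were gained without library 6 for endothelial and interferon genes (0.000733 each) and matrix genes (0.0274), and without library 11 for endothelial (0.0129), interferon (0.00307) and macrophage genes (0.0143). Fatty acid oxidation gained one without library 8 (0.00544) or 9 (0.008). Endothelial, interferon and macrophage lists were also called with the 1 TPM filter (0.0196, 0.00254 and 0.00254), median-of-ratios (0.0259, 0.0241 and 0.0239) and upper quartile rescaling (0.0239, 0.0239 and 0.031), the last of which called fatty acid oxidation too (0.0414). The fetal and stress list, lower in 11 of 16 members, was not called (median -0.31, -0.37 relative; camera adjusted p = 0.103), but was without library 8 (0.00544, relative median -0.76) and with no filter (0.0404).

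Both comparisons share the HET saline libraries, so opposite movement is partly built in. Of 645 genes that differed at least 2-fold between HET saline and WT saline, 550 lay nearer to WT saline in HET ABE, or 85.3% (exact binomial 95% interval 82.3 to 87.9, for counting error only). Simulation with no effects gave 83%, and simulation with a mutant effect that editing left in place gave 82%, ranging from 77.5% to 85.9%. The covariance of both sets of log2 differences was -0.1245, and the shared libraries alone gave -0.0961; without library 7 the difference between these turned from -0.0285 to 0.0094. HET saline stood apart from both other groups in 125 genes, WT saline in 130 and HET ABE in 125, counting genes at least 2-fold from both others while those lay within 1.5-fold.

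The third comparison asked how edited mutants, which had also received the vectors, differed from wild type. Endothelial markers were the single list called: all 11 were lower in HET ABE than in WT saline, by a median of -0.79 (-0.61 relative; camera adjusted p = 0.00369; adjusted p = 0.952 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Without library 9, matrix (0.00288), interferon (0.00727), erythroid (0.00821) and fibroblast genes (0.0304) were called lower too, with the relative fibroblast median at -0.46 against -0.18. Without library 10, calcium handling and ventricular genes were called lower (0.0496 each), and without library 11, mitochondrially encoded genes higher (8.61e-06). Matrix genes were also called lower without library 3 (0.0246) and with median-of-ratios rescaling (0.0388), and erythroid genes without library 6 (0.0251) and with both rescalings (0.0388 and 0.0203). Vwf was at 12.1 ± 0.16 TPM in WT saline and 4.86 ± 4.89 TPM in HET ABE, and Cdh5 at 15.3 ± 2.83 and 6.76 ± 2.85 TPM. Myh6 was at 42500 ± 3223 and 30460 ± 7368 TPM (log2 difference -0.51 ± 0.19, limma adjusted p = 0.483). By limma 0 genes passed, and at an unadjusted p under 0.05, 130 were higher and 951 lower, against 315 and 490 after median-of-ratios and 353 and 269 after upper quartile rescaling. They were 131 and 1470 without library 9, 238 and 662 without library 11, and 95 and 624 without library 1. Library 9 had the lowest median correlation with its own group (Pearson 0.853 across genes, which are not independent replicates). It had 613 reads per 1 M on olfactory and vomeronasal receptor genes. The other libraries had 51 to 61.3 in WT saline, 90.4 to 169 in HET saline, and 101 and 60.8 in libraries 10 and 11.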

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

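Rescaling to protein-coding genes, sample weights, counting list calls with the estimated correlation, and leaving out libraries for list calls, shares and odd groups were chosen after seeing the data, as were all alternatives for Snord14e. Snord14e kept its direction and side of the threshold in all 21 alternatives that held it for HET saline against WT saline (log2 3.87 to 5.62, adjusted p 1.13e-05 to 0.00302) and for HET ABE against HET saline (-4.79 to -3.58, adjusted p 7.55e-05 to 0.0106); rescaling to protein-coding genes removes it by construction. No paired analysis was possible because the groups share no library numbers. Random lists were planned only for 1 column per group and were not run. Where an arm kept fewer libraries, the fit pooled the spread over groups. Depth limits genes near 1 read equivalent, such as Snord14e outside HET saline.

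The count of genes in HET saline against WT saline was 2 with upper quartile rescaling, 4 with only the compared groups, 11 with sample weights and 0 with protein-coding genes alone. HET ABE against HET saline gave 2 with sample weights, and HET ABE against WT saline gave 3 with sample weights and 1 with protein-coding genes alone. Without each library the counts ranged from 1 to 4, from 1 to 7 and from 0 to 6. In the first, the count was 4 without library 11 and 2 without library 1, 2, 3, 6 or 9. In the second, it was 7 without library 10 and 2 without library 6 or 11. In the third, it was 6 without library 10, 4 without library 11, 2 without library 1 and 1 without library 2, 3, 7, 8 or 9. In the first, the gene gained without library 1 was Snora73b, another small nucleolar RNA (log2 difference 5.26, limma adjusted p = 0.000109). It was gained in the third too (5.18, limma adjusted p = 0.000127). Genes gained in the first without libraries 2, 3, 6 and 9 were Gm45841 (2.745), Gm24029 (3.66), Chchd10 (-2.98) and Gm23212 (-4.445). Large jumps were thus not limited to Snord14e once a library was left out. The cause of these counts was not tested.

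List calls in HET saline against WT saline numbered 0 with an estimated correlation, 1 with the 20 TPM filter and 19 with no filter, and 5 to 8 without each library. In HET ABE against HET saline, where 3 were called, they numbered 0 with an estimated correlation, 6, 1 and 9 with filters of 1, 20 and none, 6 with median-of-ratios and 7 with upper quartile rescaling, 5 without structural RNA and 5 with protein-coding genes alone. Without each library they ranged from 0 to 6, with 0 without library 7, 6 without library 6 and 5 without library 11. In HET ABE against WT saline, where 1 was called, they numbered 0 with an estimated correlation, 2, 0 and 16 with those filters, 3 and 2 with the rescalings, 2 with predicted genes left out and 2 with protein-coding genes alone. Without each library they ranged from 1 to 5, with 5 without library 9, 3 without library 10 and 2 without library 3, 6 or 11. The filter sets how many members and lists are tested.

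The share nearer to wild type was 89.2% with upper quartile rescaling, 80.4% with protein-coding genes alone and 76.5% at 4-fold, and 78.3% to 91.5% without each library. Genes in which WT saline, HET saline and HET ABE stood apart numbered 45, 32 and 34 with a pseudocount of 5, 249, 239 and 322 with the 1 TPM filter, 40, 36 and 21 with the 20 TPM filter, 272, 271 and 373 with none, 835, 814 and 509 at 1.5-fold and 11, 6 and 16 at 4-fold. HET ABE stood apart in 54 with predicted genes left out. Without each library the ranges were 110 to 205 for WT saline, 96 to 271 for HET saline (271 without library 6) and 108 to 241 for HET ABE (241 without library 10), and WT saline gave 205 without library 2.

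Of 110 pairs of a cardiac gene and a setting, 97 kept their direction, 13 changed it and 0 passed the threshold. In HET saline against WT saline, Nppa turned to 0.13 with a pseudocount of 5. With median-of-ratios rescaling Myh7 turned to 0.006, Nppb to 0.068, Ankrd1 to 0.083 and Atp2a2 to 0.17. With upper quartile rescaling Myh6 turned to 0.005, Myh7 to 0.20, Nppa to 0.12, Nppb to 0.27, Ankrd1 to 0.28, Rcan1 to 0.046 and Atp2a2 to 0.37, and Myh7 in HET ABE against HET saline turned to -0.037. These rescalings move the all-gene median from -0.25 to -0.02 and 0.16.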

Other observations

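The tests of small nucleolar RNA as a class, of explanations for Snord14e and for other-cell markers, of depth in library 9 and of the splits were chosen after the result was seen. Small nucleolar RNA other than Snord14e was higher in both mutant groups as a class. In HET saline against WT saline, 225 of 283 such genes were higher, with a median log2 difference of 0.43, or 0.68 relative to all genes (camera p = 3.97e-39, and p = 0.00119 with an estimated correlation). In HET ABE against WT saline, 188 of 283 were higher, with a median of 0.35, or 0.52 relative (camera p = 5.62e-24, and p = 0.00437 with an estimated correlation). Between HET ABE and HET saline the median was -0.13, or -0.20 relative (camera p = 0.000111, and p = 0.141 with an estimated correlation). Ribosomal RNA took 2.47% ± 0.337 of TPM in WT saline, 3.76% ± 0.27 in HET saline and 3.24% ± 0.941 in HET ABE (SD, n = 3), and long intergenic RNA 12.5% ± 2.01, 16.9% ± 0.456 and 17.4% ± 3.44. In libraries 9, 10 and 11 ribosomal RNA was at 2.3%, 3.22% and 4.18% and small nucleolar RNA at 7.86%, 11.9% and 13.3%. Single genes weighed heavily in the ribosomal and long intergenic shares. CT010467.1 took 2.04% to 2.67% of TPM in WT saline libraries, 3.48% to 4.01% in HET saline, and 2.24%, 3.18% and 4.16% in libraries 9, 10 and 11. Gm26917 took 7.56% to 8.13%, 10.54% to 12.38%, and 8.56%, 12.69% and 15.95%. These shares therefore need not describe other genes of either class. Snord15a was at 1396 ± 108 TPM in WT saline, 3405 ± 345 in HET saline and 3007 ± 624 in HET ABE, and Snord17 at 345 ± 49.8, 789.5 ± 38.2 and 473 ± 12 TPM. In HET saline against WT saline neither passed over all genes (limma adjusted p = 0.0875 for each), while both did with sample weights (0.0331 and 0.0358), Snord17 with upper quartile rescaling (0.0397) and Snord15a without library 11 (0.0471).

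Stk16, a protein kinase gene, was at 43.9 ± 7.48 TPM in WT saline, 12.6 ± 1.26 in HET saline and 27.4 ± 4.05 in HET ABE (limma adjusted p = 0.0831 for HET saline against WT saline, and 0.0331 with sample weights). The haemoglobin gene Hbb-bs, a member of the erythroid list, was at 31.8 ± 7.89, 9.04 ± 10.2 and 9.96 ± 10.4 TPM. Of 24 lists, 17 were not called in HET saline against WT saline (camera adjusted p from 0.0705 to 0.97), 21 in HET ABE against HET saline (0.0557 to 0.945) and 23 in HET ABE against WT saline (0.13 to 0.954). Leaving out library 8 called skeletal muscle genes higher (0.0387) in the first, and leaving out library 9 called glycolysis genes higher (0.008) in the second. By fry, 3 lists passed in the first of these comparisons and 0 in the others. The 3 were oxidative phosphorylation (fry adjusted p = 0.0345), glycolysis (0.0398, camera 0.353) and fatty acid oxidation (0.0488). Fry tests a list against no change, not against other genes, and the all-gene median was -0.25. Relative to all genes, the medians of the 3 were -0.11, -0.07 and -0.20. Called by camera but not by fry were the endothelial (0.0745), ribosomal (0.102), fibroblast (0.123), interferon (0.155) and matrix (0.162) lists.

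Snord14e was high in the 3 HET saline libraries alone. Better recovery of small nucleolar RNA is argued against as the whole cause, because the other 283 genes moved by a median of 0.43 (quartiles 0.12 and 0.78). Reads from Snord14a were not tested. Reads from Snord14c and Snord14d are argued against too. The lowest share of Snord14e relative to them in HET saline was 11.8 times the highest share elsewhere. Unspliced host RNA stays open. In 2 of the 3 HET saline libraries Hspa8 lay below the lowest WT saline library, but gene-level TPM does not separate spliced from unspliced RNA. Hspa8 was at 163.6, 55.9 and 49.8 TPM in libraries 6, 7 and 8, in the same order as Snord14e. A litter, sequence variant or library batch shared by the 3 HET saline libraries cannot be told apart from the group, since the labels give neither litter nor batch. An effect of the mutation that editing reverses also stays open and was not tested, and editing cannot be told apart from receiving the vectors.

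Endothelial and fibroblast markers were lower in HET saline, most in libraries 7 and 8, in calls that an estimated correlation ended. Macrophage (-0.46 relative to all genes) and erythroid markers (-1.13) lay lower too and missed the call. Mural markers lay at 0, or at 0.19 without Des and Abcc9. Lists too small to test lay on both sides. Schwann (3 measured) and adipocyte markers (2) were at 0.59 and 0.18, epicardial and lymphocyte markers (1 each) at -0.02 and -0.47. Fewer nuclei of every other cell type stays open: endothelial and mural markers moved apart (exact permutation p = 0.0165, across 11 and 3 genes, which are not independent replicates), but only Pdgfrb, Notch3 and Cspg4 remain as mural markers once Des and Abcc9, which cardiomyocytes express, are set aside (exact permutation p = 0.00137 with them). Less cytoplasmic RNA carried over with the nuclei also stays open, because mitochondrially encoded genes lay above the all-gene median in 2 of the 3 HET saline libraries (scores 0.31 and 0.78 in libraries 7 and 8) and below it in library 6 (-0.41). In HET saline against WT saline that list was called higher without library 6 (0.00102), with predicted genes left out (0.0225) and with protein-coding genes alone (0.0244). It was called higher with the last pair in HET ABE against WT saline too (0.0337 and 0.015), and without library 11 in HET ABE against HET saline (0.0097). A change of these cells or transcripts in the mutant heart was not tested.

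Library 9 carried 613 reads per 1 M on 1953 olfactory and vomeronasal receptor genes. Sequencing depth is argued against, since this was 3.62 times the highest other library after scaling to depth. Genomic DNA stays open: over genes silent in WT saline, the ratio of X-linked to autosomal read density was 0.268 (bootstrap interval 0.202 to 0.343), between the bound of 0.25 set beforehand to exclude DNA and the lowest ratio of 0.35 set for DNA of male mice. This ratio does not set library 9 apart, since it was 0.244 to 0.374 in the other HET saline and HET ABE libraries, and 0.631 to 0.791 in WT saline, where the genes were chosen as silent. In library 9, 42.2% of silent autosomal genes had reads, under the 50% set for DNA, and the labels do not give the sex. No biological explanation was tested.

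A hypothesis that sequence of another strain flanks the edited locus predicts more differences near Myh6 in both mutant groups. Of 137 tested genes within 10 Mb of Myh6, 6 (4.4%) had an unadjusted p under 0.05 in the same direction in both groups against WT saline, as did 407 of 11317 other genes (3.6%). The one-sided Fisher exact p was 0.373, which leaves this open.

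Each comparison of 3 against 3 libraries has 10 splits, too few for a share under 0.05. In HET saline against WT saline, 3 of the 10 splits gave at least the real count of 1 gene, and the highest other gave 1. In HET ABE against HET saline, 8 did, with a highest other of 2 against the real 1. In HET ABE against WT saline the real count was 0, which all 10 splits reach by construction (highest other 1), so that count tests nothing. For the 125 genes in which HET saline stood apart, 18 of 100 label assignments gave as many, with a highest other of 208, so chance is not excluded. For the covariance beyond the shared libraries (-0.028), 9 of 100 assignments were as low, with -0.068 the lowest other, so chance is not excluded there either.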
